A study of Mus musculus with 3 samples.

How the data were processed

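RNA was sequenced from 3 samples of KH2 mouse embryonic stem cells with an inducible knockout of Pold3, 1 library each from passages P0, P1 and P2. Total RNA was purified with a column kit and libraries followed standard Illumina procedures, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to library size) for 50043 gene IDs. Bowtie2 2.0.6, TopHat2 2.0.9 and the genome build mm9 are named per the submitters' processing notes. The program that counted reads, its annotation and the strand of the libraries are not given in the sources used here. The gene IDs fit a later annotation than the build named, so no coordinates are given and chromosome names came from GENCODE release M21.

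Of the IDs, 372 are the authors' own models without an Ensembl ID, 49326 Ensembl IDs matched a gene symbol and 345 did not. Before the data were examined, the comparisons, 33 gene lists, thresholds, alternatives and the rule for named genes were fixed. FPKM equals whole reads divided by gene length and library total, so reads were recovered by searching for totals and lengths that make all values whole. Of 26291 IDs above 0, 26288 (99.99%) gave whole reads in all 3 libraries within a relative tolerance of 1e-09, and 0 of 500 genes did so by chance with changed totals. The totals were 23213528 reads at P0, 18059914 at P1 and 22405670 at P2. A common factor of reads and length cannot be resolved for each gene, and the multiple nearest to the mean length of the M21 transcripts was used. Recovered reads summed to 101% of the totals (100.51, 100.50 and 100.50%), which may come from that choice. The cause of the excess was not tested. Of the IDs, 83.7% had a length within 1 base of that mean.

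At the depth of P0, 3 reads on a gene of 2 kb would be worth 0.0646 FPKM, at P1 0.0831 and at P2 0.0669. Intervals on ratios of FPKM are exact conditional 95% intervals (Clopper-Pearson) on the recovered reads of 2 libraries. They compare libraries, not conditions, and cover counting error only, since reads without molecular identifiers are not independent molecules.

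Values were compared as log2(FPKM + 1), a scale that understates the change of low genes. A gene counted as changed when this differed by at least 1 between libraries, among genes with FPKM of at least 1 in 1 or both of them. With 1 library per passage there was no replicate test. Counting error was simulated in 100 data sets drawn with no change. The steps were tested on simulated data for P2 against P0 with 26288 genes, where 3-fold rises were recovered for 50 of 50 genes, 3-fold falls for 46 of 50 and 1.5-fold rises for 0 of 50, with 58 calls among 26088 unchanged genes. Of 100 lists drawn at random from the simulated genes with FPKM of at least 1, changed genes not left out, 5 fell outside the limits. Random draws give about this share by construction. This checks the ranking step only, not the limits for lists of genes that vary together.

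Each list's median was ranked among 10000 random lists of the same size, drawn from 20 bins of mean expression over genes with FPKM of at least 1 in 1 or more libraries. Lists stood apart below percentile 2.5 or above 97.5, and lists with fewer than 5 measured members are given as values. Named genes are Pold3 and Pold1, Pold2 and Pold4; the 10 largest rises and 10 largest falls against P0 at each passage and the 5 and 5 of P2 against P1 among genes with FPKM of at least 5 in 1 or both libraries, leaving out unnamed models and short RNA genes; up to 4 members of each list with the largest change between P0 and P2; and Pou5f1, Nanog, Sox2, Cdkn1a, Mdm2, Terf1, Tert, Zscan4c and Zscan4d. Gene families with near-identical copies, overlapping genes and antisense genes are uncertain, since reads could be shared or assigned on either strand.

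The alternatives were a pseudocount of 0.1, a floor of FPKM 5 or none, median-of-ratios scaling, rescaling to 1000000 per library, quantile normalization, leaving out short RNA genes and unnamed models and, for chromosomes, a mean FPKM of at least 5 in place of 1. Chosen after seeing the data were thinning the recovered reads to the depth of P1 and leaving out list members that another list holds too. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.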

Results

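Gene expression was measured by RNA sequencing in mouse embryonic stem cells of the KH2 line, in which the Pold3 gene can be knocked out by induction. Pold3 encodes an accessory subunit of DNA polymerase delta, the enzyme that copies the lagging strand during DNA replication. There were 3 libraries, 1 each from passages P0, P1 and P2, so no difference below has a replicate check and no p-value is given. The labels do not say when the knockout was induced relative to P0. The totals behind the FPKM values were 23213528 reads at P0, 18059914 at P1 and 22405670 at P2. Genes with FPKM of at least 1 numbered 12303, 13015 and 13137. The study's design asks how the transcriptome differs between passages, and the comparisons are P1 against P0, P2 against P0 and P2 against P1. In what follows a gene rose or fell when log2(FPKM + 1) differed by at least 1. Counts of genes past 2-fold use this scale, which asks for more than 2-fold in FPKM itself, most of all in low genes. Ratios of FPKM carry exact 95% intervals that cover counting error only.

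Pold3, on chromosome 7, fell from 49.2 FPKM at P0 to 13.0 at P1 and 11.6 at P2. It was 3.78-fold lower at P1 than at P0 (interval 3.32 to 4.31) and 4.23-fold lower at P2 (interval 3.74 to 4.79). The library at P2 held 317 Pold3 reads against 286 at P1, and the ratio of P2 to P1, 0.893, had an interval of 0.759 to 1.05. The catalytic subunit Pold1 measured 119, 137 and 141 FPKM and the subunit Pold2 235, 202 and 210 FPKM, all within 2-fold. Pold4, the smallest subunit, was low throughout, at 1.80, 4.02 and 3.63 FPKM from 38, 66 and 74 reads.

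Between P0 and P1, 548 genes rose and 73 fell among 13288 compared. Data sets simulated with counting error and no change gave means of 29.2 and 31.5 genes, with maxima of 48 and 47. Pold3 had the second largest fall under the rule for named genes, after Stra8, a gene induced at entry into meiosis, which fell from 12.2 to 2.28 FPKM. Chac1, a glutathione-degrading enzyme induced by ATF4, fell from 25.9 to 6.56 FPKM. Lefty1 and Lefty2, which encode inhibitors of Nodal signalling, fell from 67.2 to 22.0 and from 57.8 to 23.4 FPKM. The zinc finger genes Zic2 and Zic5 fell to 8.84 and 6.03 FPKM, the linker histone gene H1f0 to 8.45 and the macroH2A gene H2afy2 to 8.02. The noncoding RNA Halr1 fell from 34.4 to 11.2 FPKM.

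The largest rises at P1 included Trp73, a p53 family member, from 3.48 to 20.5 FPKM (5.90-fold, interval 5.05 to 6.92). Sfn, the 14-3-3 sigma gene, rose from 100.3 to 465 FPKM (4.64-fold, interval 4.47 to 4.81), and the drug efflux transporter gene Abcb1b from 20.4 to 106 FPKM. The iron exporter gene Slc40a1 rose from 1.11 to 10.9 FPKM and the gluconeogenic enzyme gene Fbp1 from 1.57 to 12.2 FPKM. Nkx2-9, a homeobox gene, rose to 16.7 FPKM, Ltb4r1, a leukotriene receptor gene, to 8.94, and Cpz, a carboxypeptidase gene, to 10.7. The epidermal genes Krtdap and Sbsn reached 10.1 and 5.65 FPKM from 4 and 11 reads at P0, and the interval of the Krtdap ratio ran from 7.53 to 76.6.

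Between P0 and P2, 905 genes rose and 156 fell among 13472 compared, where simulated counting error gave means of 24.4 and 25.3 and maxima of 36 and 41. Fbp1 reached 26.0 FPKM (16.5-fold, interval 11.7 to 24.1) and its paralog Fbp2 23.2 FPKM (9.90-fold, interval 7.76 to 12.8). Sct, which encodes the hormone secretin, rose from 2.07 to 29.6 FPKM, Ccno, a cyclin-like gene, from 1.75 to 22.4, and Slc5a5, the iodide transporter gene, from 1.03 to 13.6. Trp73 reached 30.8 FPKM, Nkx2-9 29.1, Krtdap 12.5, the mucin gene Muc3 27.6 and Ms4a10 8.93. Chac1 was 8.72-fold lower at P2 (interval 7.15 to 10.7), at 2.97 FPKM. The ETS factor gene Etv1 fell from 19.9 to 4.19 FPKM, the kinase gene Dclk2 from 12.3 to 2.56 and the immediate early gene Egr1 from 29.3 to 8.72. Zic2, Zic5, H2afy2, Lefty1 and Lefty2 were at 5.71, 4.73, 6.71, 20.8 and 17.5 FPKM.

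**Figure D1:**
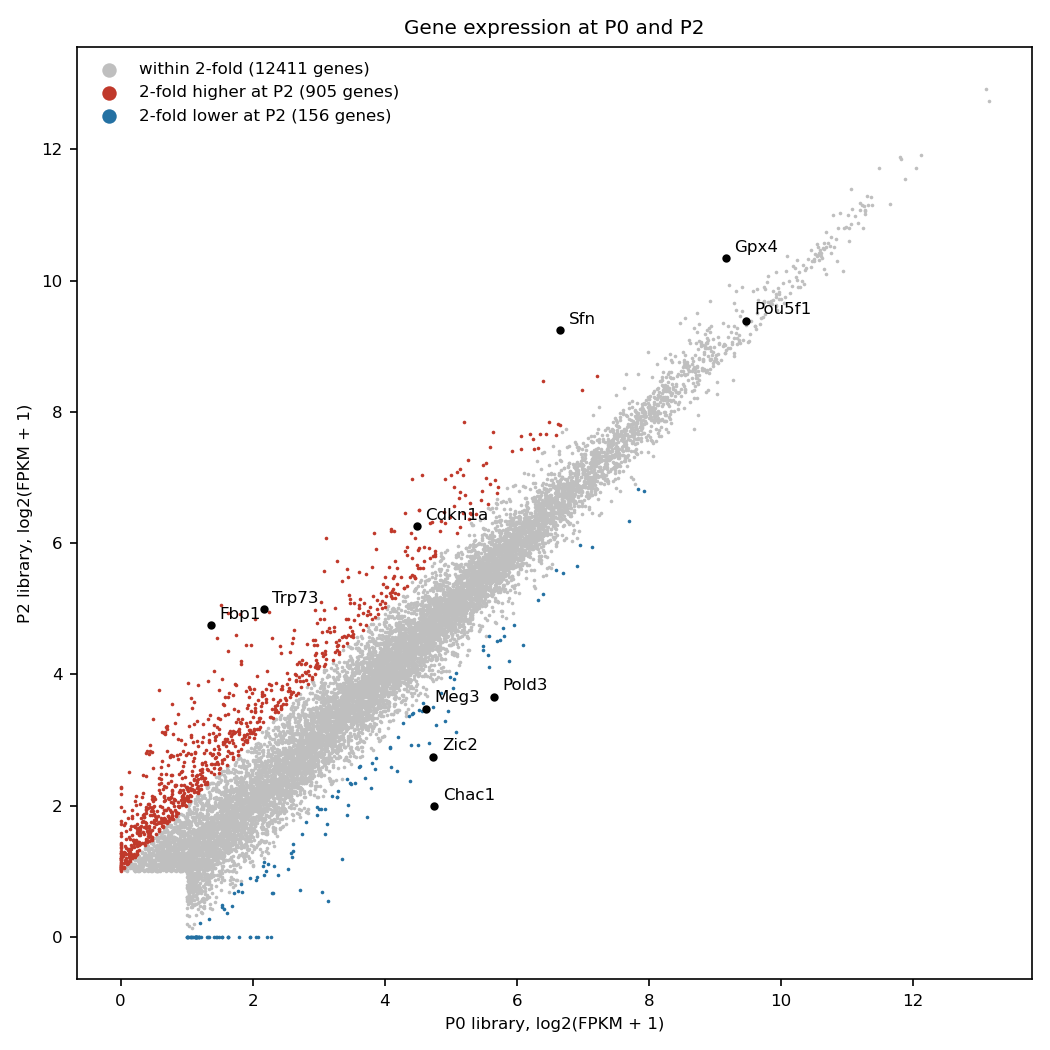
Each point is 1 gene with FPKM of at least 1 in the P0 or P2 library, placed by log2(FPKM + 1) at P0 (horizontal) and P2 (vertical), with genes past 2-fold in colour. The 905 genes that rose outnumber the 156 that fell, and Pold3 lies among the latter.

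Rises outnumbered falls at both later passages: 88.2% of the changed genes were higher at P1 and 85.3% at P2. Quantile normalization, which gives all libraries the same distribution, moved these shares to 75.2% and 70.5%. Of the 548 genes that rose by P1, 438 (79.9%) were also 2-fold above P0 at P2, and of the 73 that fell, 43 (58.9%) were also below. Both comparisons share the P0 library. With no change, simulation gave means of 5.40 and 10.2 shared genes, which was 18.5% and 32.3% of the genes past 2-fold at P1. Among the 13002 genes compared at both passages, 496 rose by P1 and 789 by P2 while 73 and 156 fell, and independent lists of these sizes would share 30.1 and 0.876 genes; part of the excess may come from the single shared P0 library. Of the genes that rose by P1, 355 (64.8%) were further from P0 at P2 than at P1, as Btg2 and Fbp1 were, and of those that fell, 23 (31.5%) were. Most of the genes that fell by P1 were thus not further from P0 at P2. Simulated counting error alone gave a mean of 31.5 falls at P1, against 73 here, but 29.2 rises against 548. Counting error may thus make up much more of the falls, so the 2 shares cannot be compared. Among genes past 2-fold at P1 in the simulations with no change, 8.65% of the higher and 4.03% of the lower were further at P2. Those genes passed 2-fold by counting error alone and so mostly fell back. Their shares are no baseline for genes that did differ at P1.

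Genes commonly reported as targets of the tumour suppressor p53 rose as a group. Of 39 measured members, 15 rose by P1 and 20 by P2, and none fell. The list's median was 0.79 at P1 and 1.06 at P2, above all 10000 random lists matched on mean expression, as a description of these libraries. Cdkn1a, the cell cycle inhibitor p21, rose from 21.4 to 63.6 and 75.6 FPKM, which was 3.53-fold at P2 (interval 3.22 to 3.88). Mdm2, the ubiquitin ligase that targets p53, rose from 89.0 to 215 and 230 FPKM. The antiproliferative gene Btg2 rose from 13.3 to 70.1 FPKM at P2, the peptide transporter gene Tap1 from 2.55 to 17.5 and Dcxr, a reductase gene, from 18.8 to 87.2. The list of p53 and its regulators had a median of 0.01 at P2 within the random range. Its 9 measured members included Trp73, which rose, and Ppm1d, Rchy1 and Usp7, which differed by 0.92, 0.34 and -0.51 on the log2 scale. The list's mean at P1 was 0.25 and its median -0.03.

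**Figure D2:**
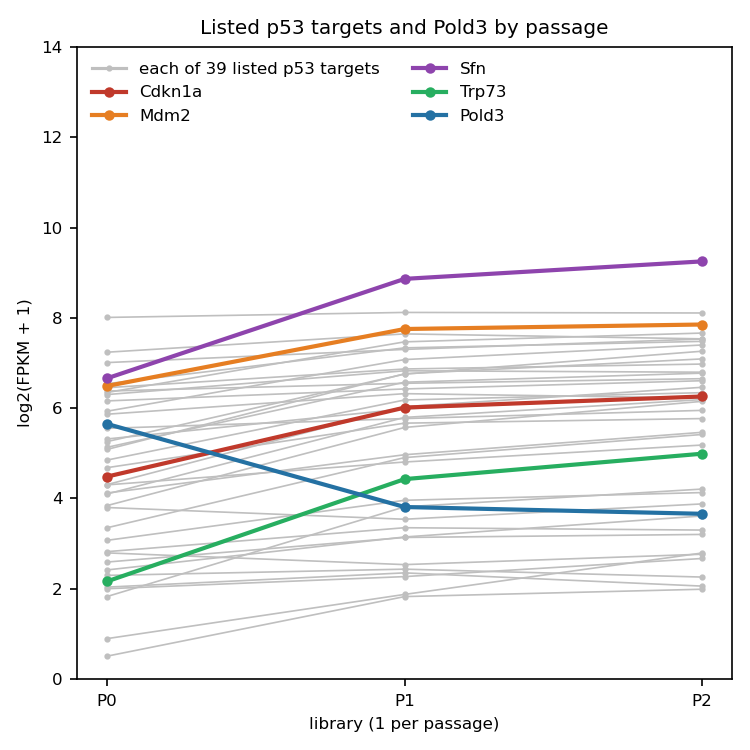
Lines join log2(FPKM + 1) in the P0, P1 and P2 libraries, 1 per passage, for 39 listed p53 targets (grey or coloured), Sfn and Pold3. Cdkn1a, Mdm2 and Trp73 rise from P0 to P1 while Pold3 falls from 49.2 to 13.0 FPKM.

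Lists for DNA replication and repair moved little. The replisome list, which leaves out Pold3 itself, had a median of 0.06 at P1 and 0.19 at P2, the latter above the random range, and 0 of its 45 members passed 2-fold. Its largest differences were in Pold4, Rfc2, Cdc6 and Orc6, at 0.73, 0.58, 0.57 and 0.50 at P2. In FPKM itself Pold4, a low gene, was over 2-fold above P0 at both later passages. Homologous recombination and Fanconi genes had a median of 0.12 at P2, with 0 of 36 past 2-fold, and Slx4 and Fanci at 0.65 and 0.58. End joining genes had a median of 0.02 with Nhej1 rising from 4.70 to 10.7 FPKM. Translesion polymerase genes, also listed without Pold3, had a median of -0.01 and a mean of 0.03. In that list Polk rose from 4.34 to 11.2 FPKM while Rev3l and Usp1 differed by -0.48 and -0.34. Checkpoint signalling genes had a median of -0.10, with H2afx, Hus1, Cdc25c and Etaa1 at -0.35, -0.44, -0.33 and -0.27. The apoptosis list had a median of 0.05, and Apaf1 and Bad rose from 20.3 to 53.6 and from 15.1 to 31.5 FPKM. It shares no member with the p53 target list used here, which does not mean that none of its genes is a p53 target. Telomere genes had a median of 0.01. The telomerase RNA Terc reached 3.69 FPKM from 7 and then 35 reads, while Tert measured 4.59, 6.08 and 5.55 FPKM and Terf1 55.5, 39.9 and 44.1.

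Among cell cycle genes, those of G1/S had medians of 0.18 and 0.21, both above the random range. Genes that restrain entry into S phase moved both ways. Cdkn2a, Cdkn2b and Rb1 reached 13.5, 4.58 and 30.9 FPKM at P2, while Cdkn1b fell from 13.5 to 4.89. G2/M genes had a median of -0.01 at P2 and cohesin and condensin genes -0.09, with none of 36 and 22 members past 2-fold. Mki67, a proliferation marker, differed by -0.65 at P2 and Pttg1, the securin gene, by 0.62. Replication-dependent histone genes lay below the random range, with medians of -0.25 and -0.33. Their messages lack poly(A) tails and the library protocol beyond the use of total RNA is not given in the sources used here. Hist1h2bc and Hist1h3g fell by P1, the latter from 23 to 5 reads.

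The naive pluripotency list lay below the random range at P1 and P2, with medians of -0.20 and -0.17. Without 5 members that other lists hold too, among them Tet1, Tet2 and Gbx2, the median at P2 was -0.09, within the range. Of 38 members only Klf4 and Fbxo15 passed 2-fold at P2. Klf4, a reprogramming factor, fell from 229 to 113 FPKM, and Fbxo15 rose from 37.7 to 81.3. Pou5f1 measured 712, 746 and 670 FPKM, Nanog 179, 165 and 240 and Sox2 274, 229 and 212, with all differences within 2-fold. Tfcp2l1 and Gbx2 differed from P0 by -0.98 and -0.92 at P2. The primed epiblast list lay above the random range with medians of 0.42 and 0.31, and its members moved both ways. Nodal, a TGF-beta family ligand, rose from 35.2 to 129.7 FPKM (3.68-fold, interval 3.49 to 3.89), as 3 other members did, while Lefty1, Lefty2 and Zic2 fell.

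Several lists of lineage markers lay above the random range at P2. At P0, FPKM of at least 1 was reached by 9 of 17 measured trophoblast genes and 6 of 11 mesoderm genes. For endoderm this was 13 of 19 and for neuroectoderm 13 of 15. The other measured members reached it only in a later library. Among 17 measured trophoblast genes 2 rose by P1 and 11 by P2, with medians of 0.67 and 1.12, above the random range both times. Gata3 reached 2.54 FPKM, Krt19 11.0 and Hand1, which is also in the mesoderm list, 7.11, from 0.827 at P0. The mesoderm list had medians of 0.27 at P1, within the random range, and 0.85 at P2, above it. Wnt3 rose from 0.672 to 5.72 FPKM and Msx2 from 2.04 to 6.48. Endoderm markers had medians of 0.39 and 0.36, above the range, with Sparc, Col4a1, Cxcr4 and Plat among 5 members that rose by P2. The endoderm median came inside the range at P1 with no floor (0.16), and at P2 with a pseudocount of 0.1 (0.38), a floor of FPKM 5 (0.20) and quantile normalization (0.15). Neuroectoderm markers had a median of -0.27 at P1, below the range, and -0.06 at P2, within it. The value at P1 was 0.06 with a floor of FPKM 5 and -0.02 with none, both within the range. Dll1 and Neurod1 rose while Sox11 fell to 2.37 FPKM at P2.

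Germline and meiosis genes had medians of 0.35 and 0.75, above the random range at both passages. Of 30 measured members, 23 had FPKM of at least 1 at P0 and 8 rose by P2. Tex19.1, a germ cell gene, rose from 31.0 to 129.8 FPKM, Taf7l from 1.97 to 10.6, Tex101 from 0.300 to 2.92 and Tex15 from 5.91 to 15.3. Genes of the 2-cell-like state were within the random range at P1, at 0.08, and above it at P2, at 0.99, where 7 of 16 members rose. Among them Gm5662, Usp17le, Zscan4a and Gm8300 reached 7.52, 5.95, 2.62 and 3.65 FPKM. Zscan4c and Zscan4d differed by 0.90 and 0.95. These genes belong to families of near-identical copies, so reads are not assigned to single copies with certainty. Copies that share reads are not separate members, so the median, the 7 of 16 and the place against random lists may count 1 signal several times. Of the 16 measured members, 4 had FPKM of at least 1 at P0, and the others reached it only in a later library. Summed over the 6 Zscan4 genes, reads numbered 197, 165 and 616, a ratio of 3.24 between P2 and P0 (interval 2.76 to 3.82).

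Fibroblast markers, listed because stem cells are often grown on fibroblast feeder layers, had medians of 0.49 and 0.76, above the random range. Of 17 measured members, 12 had FPKM of at least 1 at P0 already. S100a6, Timp3 and Col1a1 rose, to 59.0, 5.88 and 7.09 FPKM at P2. Blood cell markers with measurable levels were 3, of which Cd68 and Laptm5 rose to 30.7 and 203 FPKM and Cd3e was at 1.67. Eif2s3y was the 1 of 8 Y-linked genes measured, and it rose from 0.745 to 2.98 FPKM. Interferon response genes had medians of 0.17 at P1 and P2, within the random range, and Ifi35 was the 1 member of 18 that rose by P2.

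Genes of the integrated stress and unfolded protein responses lay below the random range, with medians of -0.19 and -0.29. Of 24 members, 6 fell by P2 and 1 rose. The transcription factor gene Atf4 fell from 141 to 60.5 FPKM (2.33-fold lower, interval 2.20 to 2.46), the folate enzyme gene Mthfd2 from 119 to 49.2 and Chac1 as given above. Atf3, which is also induced by other stresses, rose from 2.82 to 10.5 FPKM. Heat shock genes had a median of 0.23 at P1, above the range, and 0.04 at P2, within it. Cryab, Hspa1a and Hspa1b rose to 13.5, 5.87 and 21.1 FPKM at P2 and Hspb1 differed by 0.87.

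Metabolic lists moved by small amounts. Glycolysis and hypoxia genes had medians of -0.08 at P1, within the range, and -0.17 at P2, below it. Hk2, Pfkp and Pdk1, which act in or gate glucose use, fell to 34.1, 26.0 and 61.4 FPKM at P2. Cytosolic ribosomal protein genes had medians of -0.08 and -0.17, the latter below the range, with 0 of 74 past 2-fold, and the value at P2 came inside it under quantile normalization (-0.04). Respiratory chain genes had medians of 0.01 and 0.02 and sterol synthesis genes -0.04 and 0.03, all within the range. DNA methylation genes had a median of 0.01 at P1 and -0.20 at P2, the latter below the range, with Tet1 and Tet2, which are also in the naive pluripotency list, at -0.81 and -0.67 and Mbd2 at 0.91. Without the 8 of 18 members that other lists hold too, the median at P2 was -0.05, within the range. Imprinted genes were above the range at P1, at 0.36, though within it with no floor (0.17), and within it at P2, at 0.12. Igf2, a fetal growth factor gene, rose from 2.71 to 20.9 FPKM and H19 to 4.57, while Grb10 and Meg3 fell to 109.8 and 10.1 FPKM.

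**Figure D3:**
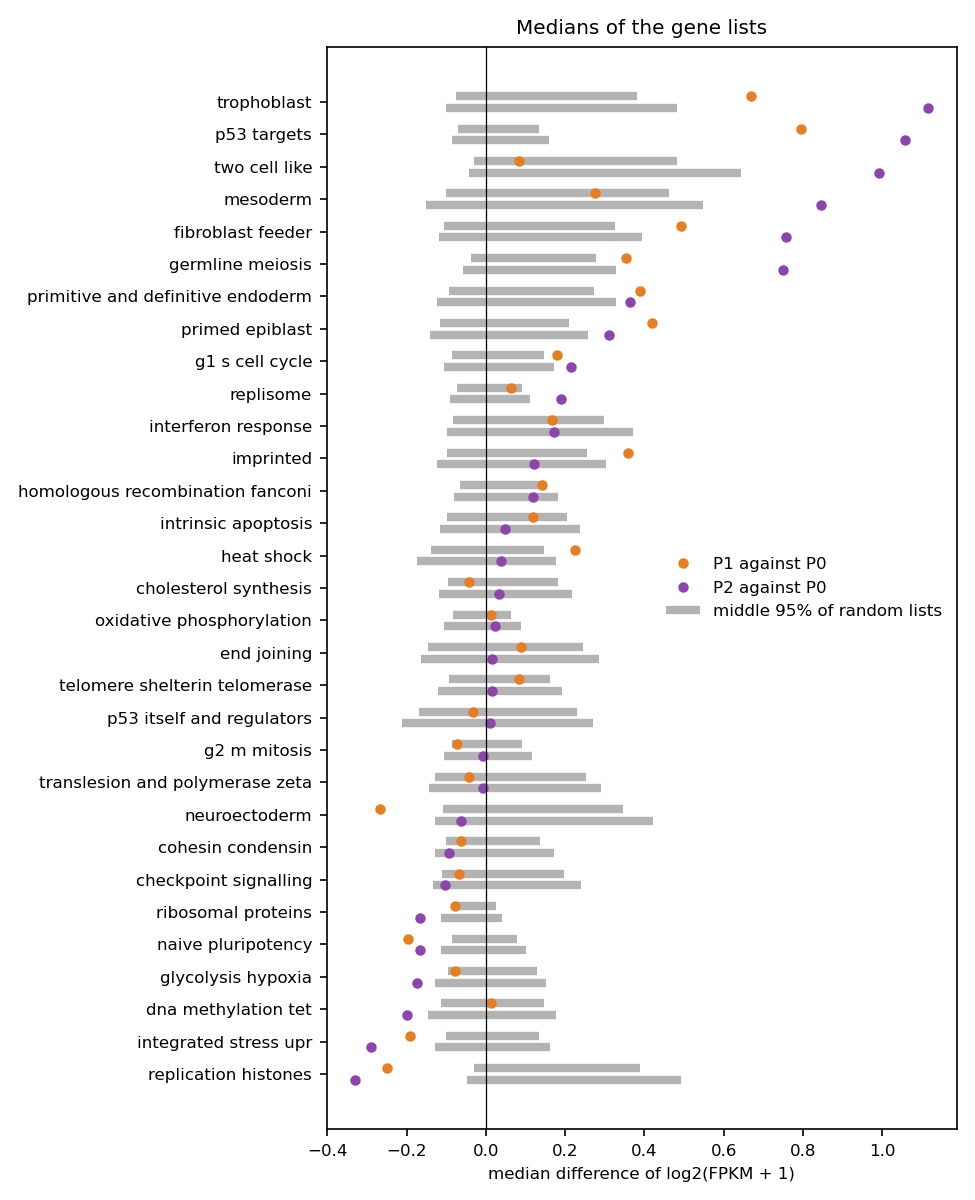
Points give the median difference of log2(FPKM + 1) of each gene list at P1 (orange) and P2 (purple) against P0, and grey bars the middle 95% of 10000 random lists matched on mean expression. The p53 targets lie at 0.79 and 1.06, beyond their bars, and the 2-cell-like genes move beyond their bar at P2.

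P2 and P1 differed less, with 106 genes higher and 120 lower at P2 among 13585 compared, against simulated means of 31.3 and 31.1. Aqp3, a water and glycerol channel gene, rose from 28.2 to 129.9 FPKM (4.61-fold, interval 4.21 to 5.06). Gpx4, which protects against lipid peroxidation, measured 573, 499 and 1298 FPKM, and was 2.60-fold higher at P2 than at P1 (interval 2.53 to 2.68). Stra8 and Cdx1 measured 12.2, 2.28 and 13.2 FPKM and 4.60, 1.17 and 6.38 FPKM, so both returned above 2-fold from a low at P1. Guca1a rose from 3.37 to 12.8 FPKM. The imprinted noncoding RNAs Meg3 and Rian fell from 38.8 to 10.1 and from 119 to 50.6 FPKM, and Egr1, Syt5 and Snhg11 fell to 8.72, 2.74 and 2.51. Among genes lower at P2, 41 were snoRNA genes, 18 snRNA genes, 18 microRNA genes and 15 protein-coding genes, and among genes higher at P2 these classes had 4, 10, 11 and 53. The classes had 97, 52, 58 and 12262 genes compared. Few reads lay behind the snRNA genes (133 at P1 and 158 at P2 in all) and the microRNA genes (357 and 488), so counting error is large for them. Without short RNA genes and unnamed models, 38 genes rose and 20 fell.

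Lists that differed between P2 and P1 included the p53 targets (0.20, with 0 of 39 past 2-fold), the 2-cell-like genes (0.96), trophoblast (0.47), germline (0.45), mesoderm (0.43) and sterol synthesis (0.11) lists, all above the random range. Below it were the glycolysis (-0.18), imprinted (-0.14), primed epiblast (-0.13), stress response (-0.11) and ribosomal protein (-0.07) lists. Of these, trophoblast came inside the range with a floor of FPKM 5 (0.19), mesoderm (0.13), imprinted genes (-0.05) and sterol synthesis (0.10) with no floor, and ribosomal proteins (-0.01) and sterol synthesis (0.09) under quantile normalization. Other medians stayed outside the range and moved by over 1.5 times. With a pseudocount of 0.1 these were 2-cell-like genes at P2 (1.83) and for P2 against P1 (1.58), trophoblast at P1 (1.19) and for P2 against P1 (0.73), and neuroectoderm (-0.46) and replication histones (-0.45) at P1. With a floor of FPKM 5 they were fibroblast markers (0.89) and endoderm (0.23) at P1 and mesoderm (1.30) and glycolysis (-0.29) at P2. With no floor they were fibroblast markers at P1 (0.28) and P2 (0.49), mesoderm (0.38) and replication histones (-0.18) at P2. Under quantile normalization they were fibroblast markers (0.31), endoderm (0.22), germline (0.20), G1/S (0.12) and neuroectoderm (-0.49) at P1, replication histones at P1 (-0.46) and P2 (-0.55) and primed epiblast at P2 (0.19). Median and mean had opposite signs in lists within the range: for P2 against P1 in translesion polymerases (-0.04 and 0.02), recombination (0.03 and -0.02), end joining (0.02 and -0.05), naive pluripotency (-0.04 and 0.03), neuroectoderm (-0.08 and 0.02), interferon (-0.02 and 0.02), cohesin (-0.03 and 0.00) and heat shock (-0.04 and 0.07), and at P1 against P0 in DNA methylation (0.01 and -0.05) and translesion polymerases (-0.04 and 0.00).

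Autosome and X chromosome medians lay within 0.09 of that of all genes. Relative to all genes, the autosome farthest from it was chromosome 18, at -0.09 at P1 and -0.08 at P2, and the X chromosome was at -0.08 at P2 against P0 and -0.09 against P1. The 15 mitochondrial genes were at 0.12 at P1 against P0 and -0.25 at P2 against P1. Chromosome 7, which carries Pold3, was 0.04 above all genes at P1 and 0.01 above them at P2, and for P2 against P1 it was at -0.02. Chromosomes 3 and 13 were at -0.07 and -0.08 at P2 and chromosomes 8 and 11 at 0.04. Chromosome medians were also ranked among random lists matched on mean expression. At P2 against P0, chromosomes 3, 13, 18 and X lay below the random range and chromosomes 2, 8, 9 and 11 above it. Chromosome 7 lay above it at P1 and below it for P2 against P1. Genes of 1 chromosome are not independent of each other, so these places only describe the libraries.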

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

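Thinning of reads to equal depth was chosen after seeing the data; it left all 6 counts of changed genes within 1.5 times their values, and the p53 target median at P2 was 1.03. Leaving out members that another list holds too, also chosen after seeing the data, brought naive pluripotency (-0.0911) and DNA methylation (-0.0516) at P2 inside the random range and changed no other list's place. Median-of-ratios scaling kept the direction and the side of the limits in all 48 cases of counts, lists outside the random range and Pold3. It left the other lists inside the range, where some medians near 0 changed sign, such as respiratory chain genes at P2 from 0.02 to -0.03; among single genes it moved 4 inside the 2-fold limit and 1 outside. Dropping the floor leaves the counts as they were by construction, since a 2-fold difference with a pseudocount of 1 needs FPKM of at least 1. With a pseudocount of 0.1, which gives low genes more weight, genes higher and lower numbered 1079 and 175 at P1, 1569 and 286 at P2, and 370 and 265 for P2 against P1. A floor of FPKM 5, which compares fewer genes, gave 310 and 32, 512 and 87, and 41 and 43, and 90.0% of the genes that rose by P1 were then higher at P2. Rescaling all libraries to 1 sum gave 122 lower genes at P1 and, for P2 against P1, 183 higher and 197 lower. Quantile normalization gave 127 lower genes at P1 and 260 at P2. Without short RNA genes and unnamed models 36 genes were lower at P1, 74 at P2 and, for P2 against P1, 38 were higher and 20 lower. The split for P2 against P1 went from 46.9% higher to 58.3% with a pseudocount of 0.1 and 65.5% without those genes. The median of neuroectoderm markers at P1 reversed to 0.0607 with a floor of FPKM 5 and came inside the random range with none (-0.0179). With no floor, which adds members near 0, medians also came inside it for endoderm at P1 (0.16), mesoderm for P2 against P1 (0.13), imprinted genes at P1 (0.17) and for P2 against P1 (-0.0549) and sterol synthesis for P2 against P1 (0.10). Endoderm at P2 came inside it with a pseudocount of 0.1 (0.38), a floor of 5 (0.20) and quantile normalization (0.15), as did trophoblast for P2 against P1 with a floor of 5 (0.19). Quantile normalization brought ribosomal proteins inside it at P2 (-0.037) and for P2 against P1 (-0.013), and sterol synthesis (0.0908). Other lists came outside the range: with a floor of 5, glycolysis at P1 (-0.11, below) and, for P2 against P1, neuroectoderm (-0.32, below) and apoptosis (0.14, above); with no floor, 2-cell-like genes at P1 (-0.011, below, sign changed) and ribosomal proteins at P1 (-0.08, below); with quantile normalization, cohesin and condensin at P2 (-0.18, below) and the respiratory chain for P2 against P1 (0.04, above). With a floor of 5, replication histones and 2-cell-like genes had fewer than 5 members and were not ranked. The median of chromosome 6 at P1, not taken relative to all genes, reversed from 0.0225 to -0.005 with a mean FPKM of at least 5, where 4 other chromosome medians came inside and 2 outside their random range. With 1 library per passage no replicate could be left out and no paired analysis was possible. Depth limits genes with few reads most, such as Krtdap with 4 reads at P0.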

Other observations

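The tests in this part were chosen after the result was seen, except the match on gene length and GC content and the one on longer genes inside introns. Within the 2-cell-like list, the 5 genes Usp17la to Usp17le, a second tandem family beside the Zscan4 genes, held 136, 143 and 513 reads at P0, P1 and P2, a ratio of 3.91 between P2 and P0 (interval 3.23 to 4.76). Sp110 and Arg2, members of the 2-cell-like list outside such tandem families and named after their values were seen, measured 0.223, 0.656 and 2.15 FPKM and 0.211, 0.737 and 1.94 FPKM. The noncoding RNAs Meg3, Rian and Mirg, transcribed from 1 imprinted locus, together held 4576, 5067 and 2250 reads, a ratio of 1.42 between P1 and P0 (interval 1.37 to 1.48) and 0.358 between P2 and P1 (interval 0.340 to 0.376). Trp53 itself, named after its values were seen, measured 267, 261 and 269 FPKM.

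The p53 target list was higher at P2 than at P0, with a median of 1.06. The list stood at percentile 100 of random lists matched on expression, length and GC content, whose upper limit was 0.15, which argues against length and GC content. Fibroblast feeder cells would bring all their abundant messages, and the fibroblast list was higher too (median 0.76). Sparc, which is listed here as an endoderm marker, went from 126 to 321 FPKM. Yet Col1a1, Col1a2 and Col3a1 together gained 5.32 FPKM while Cdkn1a and Mdm2 gained 195. Of other genes looked at for feeders, Fn1 fell from 189 to 110 FPKM and Vim from 83.7 to 58.3 at P2. Postn was at 0 in all 3 libraries, and Lum, Dcn and Tagln measured 0.0645, 0.0243 and 0.0462 FPKM at P2. These values argue against feeder cells as the whole cause. With 1 library per passage, a difference between single cultures unrelated to passage cannot be told apart from an effect of passage or of Pold3. The hypothesis that falling Pold3 raised these genes may hold and needs replicate cultures with and without induction.

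Genes that rose outnumbered those that fell at P2 against P0. The first measure chosen for background was its rate: reads relative to library size in 1434 sensory receptor genes under 1 FPKM, silent in most tissues, had a P2 to P0 ratio of 1.27 (interval 1.13 to 1.42). The ratio was above 1 beyond counting error. It lay between the bounds set for and against a higher rate of background reads as the cause, so that stays open. A second measure was whether background reads were large enough to move a gene past 2-fold. These genes gained 0.0016 FPKM on average, but genes kept under 1 FPKM could not pass 2-fold. All 1442 receptor genes, without that limit, gained 0.0022 FPKM on average, which argues against background of that size as the whole cause. Abundant genes that fell could lift all others, but 83.8% of changed genes were still higher after median-of-ratios scaling. After quantile normalization, for which no bound was set, 70.5% were higher. Passage stays a possible explanation that these libraries cannot test.

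Genes for snoRNA were lower at P2 than at P1, with a median of -0.76 over 97 genes and 1018 and then 585 reads. MicroRNA and snRNA genes had medians of -0.52 and -0.40 too. Their summed reads, not scaled to library size, were 357 and then 488 and 133 and then 158. Relative to library size the microRNA sum was higher at P2 and the snRNA sum was not. Counting error does not account for the snoRNA difference, since the upper limit of the ratio of their reads, relative to library size, was 0.513. Inside introns of protein-coding genes, 128 genes under 200 bases had a median of -0.67, with 49 past 2-fold lower and 13 higher. Against P0, however, these 128 genes had medians of 0.44 at P1 and 0.0 at P2. MicroRNA genes were at 0.21 and 0.03, snRNA genes at 0.48 and 0.24 and snoRNA genes at 0.27 and -0.46. Of these sets only snoRNA genes had a median below P0 at P2, and the others were higher at P1. Genes under 200 bases outside such introns had a median of -0.19 (bootstrap interval -0.57 to 0.07). That interval is too wide to decide on a loss of short RNA whatever its place in the genome. The set outside such introns can also hold genes inside introns of noncoding RNA genes, since only protein-coding hosts were looked up. Longer single-exon genes inside introns had a median of -0.20 (interval -0.31 to 0.08), which leaves fewer reads from unspliced host transcripts open too. A difference in library preparation and an effect of passage cannot be told apart here.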
